A study of Mus musculus with 4 samples.

How the data were processed

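Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to measure acetylation of histone H3 at lysine 9 (H3K9ac), a mark of active promoters and enhancers, in leukaemic mouse bone marrow. Per the labels' protocols, an erythrocyte lysis step preceded crosslinking in 1% formaldehyde, chromatin was sheared by sonication during 20 min, and the libraries were prepared with a NEBNext kit. The 4 samples form 4 groups of 1 library each: H3K9ac and rabbit IgG from mice with floxed Gfi1b and the NUP98-HOXD13 transgene, without Mx-Cre (called WT by the submitters) or with it (called tg). Both names are kept here, although the WT animals also carry the leukaemia transgene. The labels do not say from how many animals a library came.

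The deposited table has 1 row per gene (9615 Ensembl genes) and holds, per the file headers, the mean and standard deviation over the gene's probes in the 2 H3K9ac libraries. It was matched to the samples by the library codes in its column names. No column matched an IgG library, so the IgG background and every comparison with it was not analysed here. BWA, SAMtools, FastQC and CASAVA 1.8.2, and the builds mm10 and GRCm38, are named in the submitters' processing notes. How probes were placed, whether duplicate reads were removed, and which program wrote the table are not given in the sources used here. The table gives gene coordinates but no probe positions, so no value can be assigned to a promoter, an intron or an exon. Of 8248 genes whose symbol is in a RefSeq table of GRCm38.p6, 8239 overlapped their position there.

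The authors' deposited values are log2 values per gene, averaged over the gene's probes. Their scale was worked out from the values. For the 7423 genes with 1 probe, 100% of the linear values in both libraries were whole multiples of 1 step, within 0.01 of a read, once the lowest value was read as 0.9 of a step. The step was 3.23 in the WT and 6.11 in the tg library, which corresponds to scaling to 1000000 with totals of 309649 and 163712 reads, and to 0 reads being entered as 0.9 of a read. Reads at genes with recovered counts, counting neighbours with identical values once, came to 91.6% and 90.4% of these totals. Genes that share only some of their probes are still counted more than once in this share. Which reads the totals include is not given in the sources used here. Each 1-probe gene had at least 9 reads over both libraries together, and genes below that level do not appear in the table.

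Read counts per probe were recovered from the mean and standard deviation for genes with 1 to 4 probes (9492 genes, 98.7%). A solution was kept only where exactly 1 set of whole numbers matched both values. The 117 genes with 5 or more probes were used with their log2 values only. Some neighbouring genes share a probe: 1555 genes had the same values as a gene within 100000 bp, and merging them left 8818 sets. Neighbours that share only some probes, as in the Hox clusters, were not merged.

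The comparison of tg with WT was the difference of the authors' log2 values. Folds with intervals were computed from reads summed over a gene's probes, scaled by the totals, with exact conditional binomial (Clopper-Pearson) 95% intervals. Summing weighs probes by their reads, while the deposited log2 values weigh all probes of a gene alike, so that the fold and the log2 ratio of a gene with several probes can differ. These intervals cover counting error only. Reads without molecular identifiers are not independent molecules. Where a library had 0 reads, the fold was computed against a floor of 3 reads in that library and is given as "at least". This value leaves out the counting error of the other library's reads. It is therefore not the lower end of a 95% interval and can lie above it. With 1 library per group there is no test between genotypes: no p-value is given, and "higher" and "lower" describe these 2 libraries. A 2-fold difference is a rule of size. The number of genes that counting error alone would put beyond 2-fold was computed from binomial draws of each gene's pooled reads at the ratio of the totals.

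Before the data were examined, 22 gene lists, the alternatives and the rule for named genes were fixed. Named were Gfi1b and its cofactor list, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes whose level reached the median of all genes, and up to 4 members per list with the largest difference (2 with the highest WT level where no member was beyond 2-fold). Unnamed gene models were passed over, and genes that share a probe were taken once. The criterion that a gene exceed IgG could not be applied. The scale of the mean level had not been fixed: the mean of the linear scaled values was used (at least 62.1 scaled reads), because a mean of log2 values removes genes with no reads in one library. Some genes that the rule names are not reported here. Members named beyond this rule were chosen after their values were seen. For each list, the median log2 ratio was ranked among the medians of 10000 random lists of the same size drawn from 10 bins of mean level. This rank describes these libraries and is not a test of the genotypes. The counting interval of a median comes from 2000 binomial redraws of its members' summed reads, with the offset between summed and deposited ratios kept fixed. Members without recovered reads, such as Tal1, Lmo2, Runx1 and Pbx3, were held at their log2 ratio. The interval leaves out their counting error and can be too narrow for their lists. After the data were seen, 5 lists were added, which the closing observations use. Older symbols were matched through the reference table (Sptb is listed as Spnb1 and Spi1 as Sfpi1).

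Alternatives were median ratio and upper quartile scaling, pseudocounts of 0.1 and 5, filters on level, thresholds of 1.5-fold and 3-fold, and averaging rows of 1 symbol. Subtraction of IgG could not be run, and peak overlaps do not apply to this table. Summed reads, a floor for genes with 0 reads, 1 row per shared probe, thinning WT to the tg depth, a filter on mean log2 values and leaving out the sex chromosomes were added after seeing the data. The scripts were tested on simulated data made from the 9492 genes of the tg and WT comparison. Recovered reads were right in all cases with a unique solution, and 9.28% of the 9292 unchanged genes went beyond 2-fold by counting error. Of genes simulated with a 2-fold change, 40% (higher in tg) and 60% (lower) passed the 2-fold rule. At 4-fold, these shares were 100% and 92%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.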

Results

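H3K9ac was profiled in leukaemic bone marrow of mice that carry the NUP98-HOXD13 fusion transgene, a model of myelodysplastic syndrome and acute myeloid leukaemia, and floxed alleles of Gfi1b. GFI1B is a transcriptional repressor of the erythroid and megakaryocytic lineages that recruits the histone demethylase LSD1 and histone deacetylases. The question put by the design is how H3K9ac differs when Mx-Cre, an interferon-inducible Cre recombinase, is present to delete Gfi1b. There was 1 H3K9ac library per genotype, the Cre-negative (WT) and the Cre-transgenic (tg) library, so no difference between them has a replicate check. The totals behind the scaled values were 309649 reads for WT and 163712 for tg, 1.89 times fewer. The median 1-probe gene rested on 22 reads in WT and 11 in tg. A count of 0 allows up to 9.69 scaled reads (3 reads) in WT and 18.3 in tg. The Y-linked genes differed between the animals sampled: Uty had 28 reads in WT and 0 in tg, and Ddx3y had 22 and 1. The WT library thus carried Y-chromosomal H3K9ac that was almost absent from tg.

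Across the 9615 genes with at least 1 probe, 1586 were at least 2-fold higher and 1522 at least 2-fold lower in tg, while the median gene was nearly equal (median log2 ratio 0.045, SD over genes 1.27). Levels of the 2 libraries correlated across genes with a Spearman coefficient of 0.57, and genes are not independent replicates. Among the 7423 genes with 1 probe, 1063 were 2-fold higher and 1192 lower, where counting error alone would give 297 and 458. Among the 4221 of them at or above the median level, 375 were higher and 468 lower against 44 and 89 from counting error. In the best covered 2275 genes, at or above the upper quartile, 127 and 198 passed against 6 and 17. At 22.5% of the 1-probe genes the tg reads lay outside the 95% range that counting error allows. Part of every count beyond 2-fold is therefore counting noise, most of all among weakly covered genes.

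**Figure D1:**
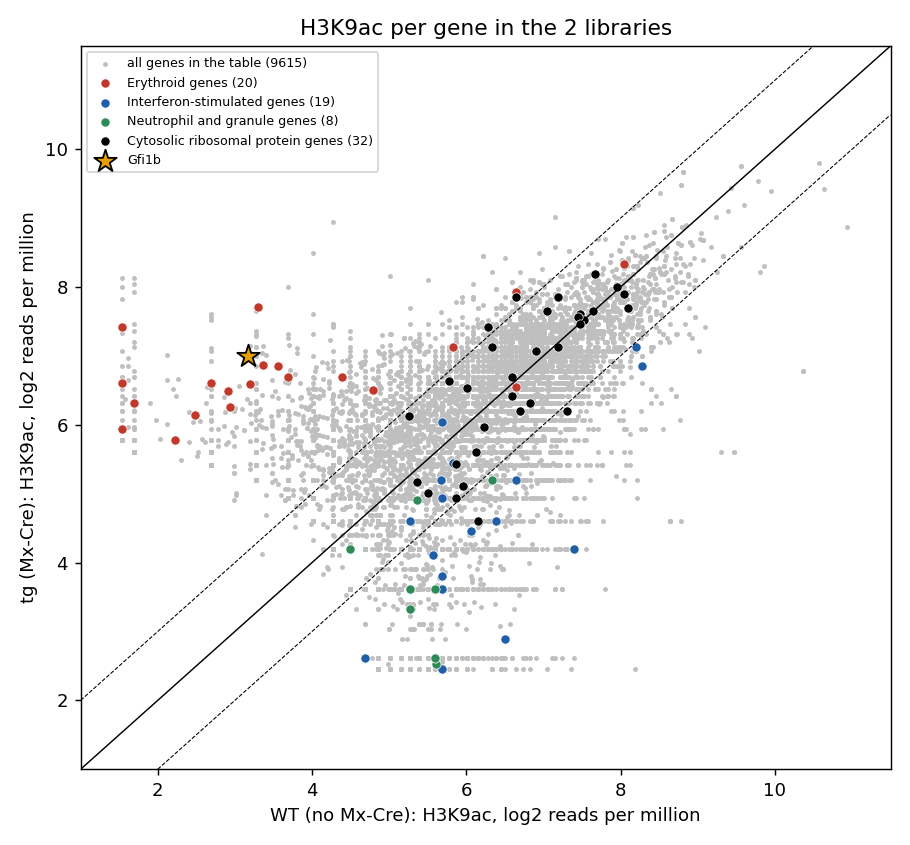
Log2 H3K9ac reads, scaled to 1000000, per gene in the WT library (x axis) and the tg library (y axis); each point is 1 gene, the solid line marks equal levels and the dashed lines 2-fold differences. Of the 20 erythroid genes (red), 18 lie above the upper dashed line, whereas 14 of 19 interferon-stimulated genes (blue) and 6 of 8 neutrophil genes (green) lie below the lower one.

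Gfi1b itself carried far more H3K9ac in the library of Cre-transgenic marrow. Its 4 probes (gene at chromosome 2, 28609450 to 28621982, GRCm38, ENSMUSG00000026815) held 12 reads in WT and 108 in tg, a 17.0-fold higher scaled level (95% interval 9.36 to 34.0). The difference was not due to a single probe: the WT probes held 2, 2, 3 and 5 reads and the tg probes 8, 18, 23 and 59. Because probe positions are not given, a loss of reads over the floxed part could not be looked at, and this locus does not check the genotype. Of the 18 genes listed for GFI1B and its cofactor complexes, 15 had a probe, 4 were at least 2-fold higher in tg and 0 were 2-fold lower. Besides Gfi1b these were Zmym3 (1 read in WT and 8 in tg), Rcor3, a CoREST family gene (2.19-fold higher, 1.39 to 3.47), and Hdac1 (2.21-fold, 0.947 to 5.22). Gse1 was 2.57-fold higher by summed reads (1.76 to 3.78), but 1 of its 4 probes held 54 of the 68 tg reads, and its deposited log2 ratio was 0.50. Other members were nearer to equality: Kdm1a, which encodes LSD1, had a ratio of 1.12 (0.636 to 1.91), Rcor1 1.23 (0.702 to 2.11) and Hdac2 0.905 (0.518 to 1.53). Each of these 3 intervals includes 1. The list's median log2 ratio of 0.29 lay at percentile 78.7 of random lists. Erythroid genes were higher in the same tg library (median log2 ratio 3.45), and the log2 ratio of Gfi1b was 3.84.

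**Figure D2:**
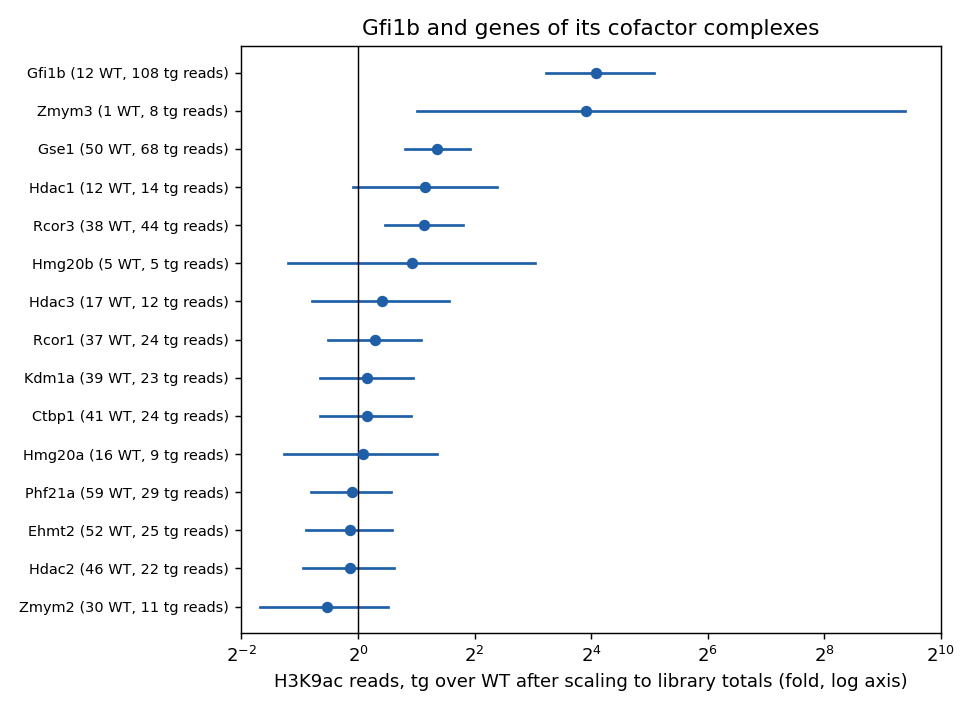
H3K9ac in tg over WT (fold of scaled reads summed over a gene's probes, log axis) for the 15 listed genes of GFI1B and its cofactor complexes that had a probe; points are the folds, lines the exact 95% counting intervals, and the labels give the reads in each library. Gfi1b stands at 17.0-fold, while Kdm1a, Rcor1 and Hdac2 lie close to 1.

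The 12 genes highest in tg held 0 or 1 read in WT. They were led by Dnaja4, a co-chaperone gene (chromosome 9, 54698873 to 54716315), with 0 reads in WT and 46 in tg, at least 29.0-fold higher, and Slc25a21 (1 and 46 reads). Next came Sphk1, which encodes sphingosine kinase 1 (1 and 43 reads), the amino acid transporter gene Slc43a1 (0 and 37, at least 23.3-fold) and the erythropoietin receptor gene Epor (0 and 28, at least 17.7-fold; chromosome 9, 21958899 to 21963576). The others were Kbtbd12 (0 and 56 reads over 2 probes, at least 35.3-fold), Nckap1 (1 and 29), the lamin A/C gene Lmna (1 and 27), Zcchc3 (0 and 22), Dusp8 (1 and 24), Popdc2 (1 and 23) and Fam109b (1 and 43). With 1 read in WT the ratios are loosely bounded, for example 87.0 for Slc25a21 with an interval of 14.9 to 3510.

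At the other end, Sirpa, an inhibitory receptor of myeloid cells (chromosome 2, 129592835 to 129632228), had 90 reads in WT and 0 in tg, at least 15.9-fold lower. The formin gene Fmnl1 had 51 and 0 reads (at least 8.99-fold lower) and the adaptor gene Lat2 41 and 0 (at least 7.23-fold). Elmo1, a regulator of Rac and of engulfment, had 47 and 1 reads, Wdfy4 44 and 1, Tm6sf1 43 and 1, and Ap1s3 37 and 1. Pmaip1, the gene of the pro-apoptotic protein NOXA, was 18.2-fold lower (4.86 to 154). The probe shared by the immunoglobulin heavy chain joining segments Ighj1 to Ighj4 (Ighj4 at chromosome 12, 113428514 to 113428567) was 16.4-fold lower, with 124 reads in WT and 4 in tg (6.24 to 61.1). Clec2i, which has the same values as its neighbour BC035044, was 14.5-fold lower (7.25 to 34.1), Tifab 12.9-fold (6.41 to 30.3) and Ms4a6c 12.4-fold (3.25 to 106).

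Genes of the erythroid lineage formed the group with the largest difference. Of the 20 listed genes with a probe, 18 were at least 2-fold higher in tg and 0 were 2-fold lower, and the median log2 ratio was 3.45 (counting interval 2.94 to 3.62), above all 10000 random lists. Setting the 3 genes with 0 WT reads at the floor gave 3.32. Besides Epor, the Rhesus-associated glycoprotein gene Rhag had 0 reads in WT and 16 in tg (at least 10.1-fold), and Gata1, the master regulator of the lineage, had 1 and 13. The carbonic anhydrase gene Car2 was 13.4-fold higher on 17 and 120 reads, the band 3 gene Slc4a1 11.0-fold (5.93 to 22.4) and Hemgn 12.3-fold (5.17 to 35.5). Alas2, the erythroid enzyme of the first step of haem synthesis, had 0 and 10 reads, and Hba-a1, whose reads may be shared with its near-identical copy Hba-a2, had 4 and 17. Klf1, an erythroid transcription factor gene already acetylated in WT, was 2.44-fold higher (1.49 to 4.04). The exceptions were Tfrc, the transferrin receptor gene, at 1.22 (0.849 to 1.75), and Bcl11a at 1.08 (0.804 to 1.45). By summed reads, 15 of the 18 genes with recovered reads were 2-fold higher, where counting error alone would give 0.446. The lists of neutrophil and monocyte markers were lower in the same tg library.

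The neutrophil and monocyte lists had lower H3K9ac in tg. Of the neutrophil list only 8 of 30 genes had a probe; 0 were 2-fold higher and 6 were 2-fold lower, with a median log2 ratio of -1.80 (-2.45 to -0.77; percentile 0.18). The myeloperoxidase gene Mpo had 31 reads in WT and 1 in tg, the gene of the granulocytic transcription factor Cebpa 15 and 1, the lysozyme gene Lyz2 24 and 3, and the proteinase 3 gene Prtn3 15 and 2. The interval of Prtn3 includes 1 (3.97-fold lower, 0.922 to 35.7). Of 9 monocyte and macrophage genes, 5 were 2-fold lower and 1 higher (median -1.67, percentile 0.08). Irf8, a transcription factor gene of monocytes and dendritic cells, was 7.42-fold lower on 407 and 29 reads (5.09 to 11.2). Ly86 was 21.9-fold lower (5.89 to 184), and Spi1, which encodes PU.1, 5.20-fold lower (2.87 to 10.3). The gene that was 2-fold higher was Csf1r, the macrophage colony-stimulating factor receptor gene, with 4 reads in WT and 9 in tg. Cx3cr1 (25 and 19 reads) and Ctss (5 and 4) had log2 ratios of 0.63 and 0.60. Among 7 dendritic cell genes, 5 were 2-fold lower and 1 higher (median -1.42, percentile 0.615). Flt3 was 3.65-fold lower (1.93 to 7.63). The toll-like receptor gene Tlr9 had 12 and 1 reads, and its interval includes 1 (6.34-fold lower, 0.939 to 271). Bst2 and Irf7, also 2-fold lower in the dendritic list, are on the list of interferon-stimulated genes as well. Flt3 is also on the stem and progenitor list. The neutrophil, monocyte and dendritic lists hold few genes with probes, and red cell lysis preceded fixation in both samples, per the labels' protocols. The erythroid list was higher in the same tg library.

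Interferon-stimulated genes were lower as a group. Of 19 with a probe, 14 were at least 2-fold lower in tg and 0 were 2-fold higher, and the median log2 ratio of -1.59 (-1.89 to -0.95) lay below all random lists. Trim30a was 21.0-fold lower on 119 and 3 reads (7.00 to 103), Xaf1 9.16-fold (2.97 to 45.9), and Gbp3 had 16 and 0 reads (at least 2.82-fold lower). Irf7, the interferon regulatory factor of the response, was 2.30-fold lower (1.27 to 4.46), Irf9 2.09-fold (1.31 to 3.46), and Bst2 2.67-fold (1.62 to 4.63). Rsad2, on 8 and 1 reads, could not be told from equality (4.23-fold lower, 0.567 to 188). Mx1, whose promoter drives the Cre transgene, had nearly equal reads for the depth (ratio 1.02, 0.562 to 1.81), as did Ifih1 (0.946, 0.578 to 1.51). By summed reads 13 of 18 were 2-fold lower against 0.941 from counting error. The neutrophil and monocyte lists were lower in the same library.

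The list of leukaemic stem cell surface and acute myeloid leukaemia genes was lower too: 10 of 18 genes were 2-fold lower and 1 was higher (median -1.07, -1.45 to -0.66; percentile 0.02). The transcription factor gene Sox4 was 3.85-fold lower (2.45 to 6.31), the DNA methyltransferase gene Dnmt3a 5.55-fold (2.01 to 21.3), the DNA demethylation enzyme gene Tet2 3.67-fold (2.12 to 6.78) and Cdk6 2.17-fold (1.63 to 2.93). Clec12a, a surface antigen of myeloid and leukaemic cells, was 3.30-fold lower (1.14 to 13.1). Npm1 was the member that was higher (2.22-fold, 1.23 to 4.05), while Myc had a ratio of 1.52 (0.933 to 2.47) and Cd47 0.848 (0.680 to 1.05). The neutrophil and monocyte lists were lower in the same library (medians -1.80 and -1.67) and the erythroid list was higher (3.45). Cebpa is on both this list and the neutrophil list.

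Stem and progenitor cell genes divided into 2 directions, with 4 of 19 at least 2-fold higher and 8 at least 2-fold lower in tg (median -0.15, percentile 22.2). Higher were Tal1 (log2 ratio 3.59 over 6 probes) and Lmo2 (3.08 over 6 probes), both members of the GATA1 and GATA2 complex, and Prdm16 and Meis1 on 2 WT reads each against 8 and 7 in tg. Lower were Cd34 (13 and 0 reads, at least 2.29-fold), Fli1 (5.23-fold, 2.73 to 11.3), Erg (3.22-fold on 292 and 48 reads, 2.36 to 4.46), Mecom (2.74-fold, 1.62 to 4.91) and Flt3. Runx1 was nearly equal (log2 ratio -0.05 over 6 probes). The list median depended on which genes were included: summed reads could be had for 16 of the 19, without Tal1, Lmo2 and Runx1, and their median was -0.69. Tal1 is also on the erythroid list and Flt3 on the dendritic list. In the same library the erythroid list was higher, and the neutrophil, monocyte and dendritic lists were lower.

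In the Hox and Meis list, which covers genes activated in NUP98-HOXD13 leukaemia, 3 of 13 genes were 2-fold higher and 1 was lower by the deposited log2 values (median 0.24, percentile 79.2). Hoxa10 had 2 reads in WT and 34 in tg (32.2-fold higher, 8.24 to 276), and Hoxc8 was 3.57-fold lower (1.24 to 14.0). Most of the reads lay elsewhere in the cluster. The tallest probe of Hoxa9, with the same counts as the tallest probe of Hoxa7, held 883 reads in WT and 294 in tg, 1.59-fold lower (1.39 to 1.82). Averaging log2 values over tall and low probes turned the direction for some genes. Hoxa3 had a log2 ratio of 1.09, whereas its summed reads were 1.48-fold lower in tg (1.16 to 1.89), and Hoxa9 had 0.87 against 1.47-fold lower (1.29 to 1.67). With reads summed per gene, 2 of 12 genes were 2-fold higher and 2 lower, and the median log2 ratio was -0.56, opposite in sign to the 0.24 of the deposited values. Neighbours such as Hoxa7 and Hoxa9 hold probes with the same counts, so these genes are not independent measurements.

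**Figure D3:**
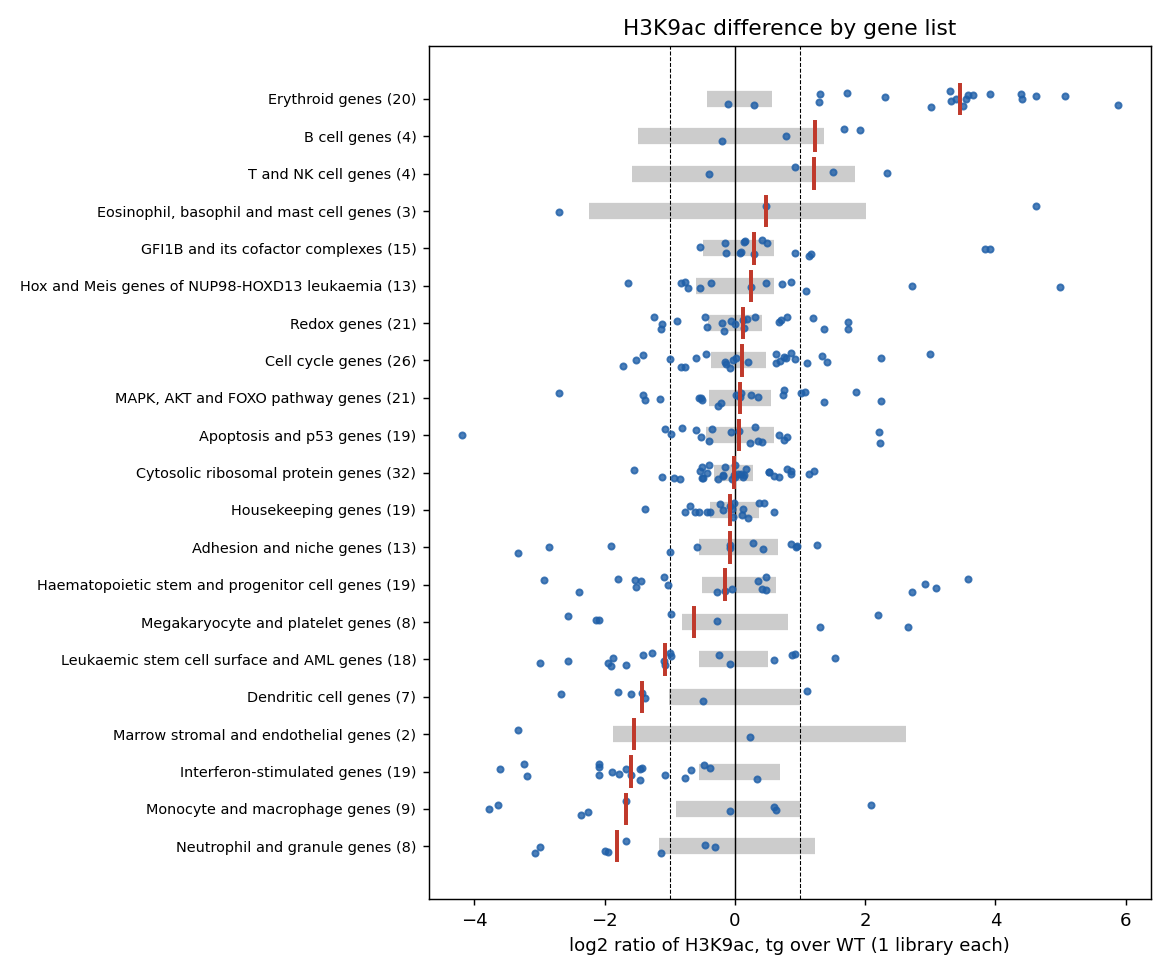
Log2 ratio of H3K9ac, tg over WT, by gene list fixed before the data were examined; blue points are genes, red bars the list medians, grey bands the central 95% of medians of 10000 random lists matched on level, dashed lines 2-fold differences, and numbers in brackets the genes with a probe. The erythroid median of 3.45 lies to the right of its band, and the medians of the interferon (-1.59), monocyte (-1.67) and neutrophil (-1.80) lists lie to the left of theirs.

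Megakaryocyte and lymphoid lists were thinly covered. Of 8 megakaryocyte and platelet genes, 3 were 2-fold higher and 3 lower: the receptor genes P2ry1 (6.30-fold, 2.44 to 19.2) and F2r (4.59-fold, 1.81 to 13.1) were higher, Plek was 4.39-fold lower (2.27 to 9.49), and Selp had 10 and 0 reads. Their median of -0.62 and their summed reads, 1.22-fold higher, differed in sign. Only 4 of 24 B cell genes had a probe, among them Vpreb1, the surrogate light chain gene (1.72-fold higher, 1.01 to 2.91), Pax5 (0.873, 0.272 to 2.46), Lef1 (3 and 6 reads) and Ralgps2 (14 and 13). Of 4 T and NK cell genes, 2 were 2-fold higher, among them Ets1 (3 and 8 reads). The eosinophil, basophil and mast cell list had 3 genes with a probe, with Gata1 higher and the histidine decarboxylase gene Hdc at 11 and 0 reads. The marrow stromal and endothelial list had 2, of which Pecam1 had 19 and 1 reads. None of the 30 liver, neuron, muscle and testis genes had a probe.

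Pathway lists did not stand apart as groups, although single members differed. Of 21 MAPK, AKT and FOXO pathway genes, 5 were 2-fold higher and 4 lower (median 0.08, percentile 51.9). Map3k5 was 4.73-fold higher (1.36 to 20.7) and Pik3r1 1.89-fold higher by summed reads (1.25 to 2.86, log2 ratio 1.86). Klf2 had 15 and 3 reads, and its interval includes 1 (2.64-fold lower, 0.748 to 14.2). By summed reads the list had 2 genes higher and 3 lower. Mapk14, which encodes p38 alpha, was among the 5 by its deposited log2 ratio of 1.36, but had a summed ratio of 1.20 (0.765 to 1.87). Foxo3 had a log2 ratio of 0.75 and a summed ratio of 0.862 (0.619 to 1.19). Of 21 redox genes, 4 were higher and 3 lower (median 0.13, percentile 73.4): the mitochondrial superoxide dismutase gene Sod2 was 3.35-fold higher (1.63 to 7.19), and the glutathione genes Gclm 3.33-fold (1.90 to 5.99) and Gsr 2.42-fold (1.49 to 3.98). Cyba, a subunit of the phagocyte oxidase, was 2.91-fold lower (1.47 to 6.40). Of 26 cell cycle genes, 5 were higher and 3 lower (median 0.11, percentile 59.5), whereas by summed reads 2 of 25 were higher and 4 lower. E2f2 was 4.09-fold higher by summed reads (2.89 to 5.86) and Ccnd3, the cyclin D3 gene, had a log2 ratio of 2.25 over 8 probes, whereas Ccnd1 was 2.64-fold lower (1.16 to 7.05) and Mcm6 2.11-fold lower (1.07 to 4.54).

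Among 19 apoptosis and p53 genes, 2 were higher and 2 lower, with a median of 0.06 and a mean of -0.05; by summed reads 2 were higher and 4 lower. The survival genes differed in opposite directions, with Bcl2l1 2.87-fold higher (1.76 to 4.76) and Bcl2 3.75-fold lower (1.93 to 8.16), and Trp53 was 2.58-fold higher (1.61 to 4.17). Of 13 adhesion and niche genes, 1 was higher and 3 were lower (median -0.08, percentile 33.2): Selplg, which encodes a selectin ligand, was 4.10-fold lower on 31 and 4 reads, and Icam1 2.41-fold higher (1.02 to 5.86). By their medians, the reference lists were centred near equality. Of 32 ribosomal protein genes, 2 were higher (Rpl14 and Rps24) and 2 lower (Rpl38 and Rpl6), with a median of -0.01. Of 19 housekeeping genes 0 were higher and 1 was lower, with a median of -0.08. That gene was B2m, the light chain of MHC class I (2.59-fold lower on 142 and 29 reads). By summed reads the housekeeping list was lower in tg (ratio 0.803, 0.722 to 0.893), whereas the ribosomal protein list was near equality (1.06, 0.974 to 1.16).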

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

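No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. Subtraction of IgG was not run. The counts of genes at least 2-fold higher and lower in tg were 1586 and 1522 of 9615. They changed by more than 1.5 times only with filters and thresholds. The filters also leave fewer genes to count. At or above the median level the counts were 493 and 519 of 4812 genes, and at or above the upper quartile 136 and 207 of 2406. With the median taken on mean log2 values, added after seeing the data, they were 377 and 449 of 4811. Over all genes, 2760 and 2445 passed at 1.5-fold, and 816 and 768 at 3-fold. Both scalings shifted all genes by under 0.1 (0.045 for the median ratio and 0.056 for the upper quartile). Of 201 alternative values of list medians, 186 stayed within the counting interval of the median. Many of these alternatives, such as the scalings, the pseudocount of 0.1 and averaging rows, hardly change a median. This count is therefore a weak check of robustness. The erythroid median stayed positive but fell outside its interval with a pseudocount of 5 (2.84) and with the filters on level. It was 2.31 at or above the median level (9 genes) and 1.29 at or above the upper quartile (3 genes). Setting the genes with 0 reads in WT at the floor gave 3.32, so these genes do not account for the fall. The erythroid difference was smaller among the better covered members that the filters keep. At or above the median level, the stem and progenitor median was 0.14 (6 genes), the megakaryocyte median 1.31 (5 genes) and the monocyte median -2.35 (3 genes). No gene of the neutrophil list reached that level. At or above the upper quartile, the stem and progenitor median was -0.95 (2 genes), the megakaryocyte value -2.13 (1 gene), the MAPK, AKT and FOXO median -0.52 (5 genes), the redox median 0.50 (8 genes) and the apoptosis value -4.19 (1 gene); each rests on fewer genes. With summed reads, added after seeing the data, the stem and progenitor median was -0.69 (16 genes), the Hox and Meis median -0.56 (12 genes), and the stromal value -3.33 (1 gene). Genes with 5 or more probes drop out, among them Tal1 and Lmo2 of the stem and progenitor list. From the Hox and Meis list only Pbx3 dropped out (log2 ratio -0.53), so the change of sign there came from summing reads over probes. Leaving out X and Y, also added later, took Gata1 from the eosinophil, basophil and mast cell list, whose median became -1.10 (2 genes). For the genes with the largest differences and Gfi1b, 25 together, 110 of 150 alternative values were unchanged or stayed within the counting interval, and 0 reversed. The 40 others were all at the 8 genes with 0 reads in 1 library, for which no interval was set. These genes were picked for their large ratios and many have wide intervals. A reversal was therefore hardly possible, and these counts are no check of robustness. Depth limits what can be said of single genes: over all 1-probe genes, each at its own reads, counting error alone puts 10.2% beyond 2-fold.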

Other observations

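Further gene lists were drawn up after the erythroid and myeloid differences had been seen. Of 29 genes of haem synthesis, iron handling and red cell membrane or transport that were not on the erythroid list, 24 were at least 2-fold higher in tg and 1 was lower (median log2 ratio 2.42). Sox6, an erythroid transcription factor gene, had 4 reads in WT and 56 in tg, the water channel gene Aqp1 4 and 47, the haem synthesis genes Cpox 12 and 43 and Alad 12 and 36, and the dematin gene, listed as Epb4.9, 0 and 42. The glucose transporter gene Slc2a1 was the exception, with 31 and 5 reads. Of 15 transcription factor genes of the erythroid and megakaryocytic lineages, 9 were 2-fold higher and 2 lower (median 1.31), among them Zfpm1 with 23 and 119 reads and Nfia with 15 and 55. Gata1, Tal1, Klf1, Nfe2, Zfpm1, Lmo2 and Foxo3 are also on lists fixed earlier.

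Of 14 myeloid and inflammatory transcription factor genes, 0 were 2-fold higher and 8 were 2-fold lower in tg (median -2.07). Reads at Irf5 were 55 in WT and 4 in tg, at Irf1 51 and 4, at Rel 104 and 13 and at Cebpb 39 and 4, whereas Zeb2 had 283 and 118 and Klf6 90 and 61. Irf8, Klf4, Spi1 and Cebpa are also on lists fixed earlier. Of 13 MHC class I presentation genes, 5 were 2-fold lower and 1 was higher (median -0.75). Psmb9, whose probe counts recur at another listed gene, had 122 and 24 reads and H2-D1 87 and 17, while Tapbp had a log2 ratio of 2.11. By summed reads 0 of the 13 were 2-fold higher and 6 were lower.

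In the weighing of 3 patterns that follows, the tests of the haem genes and of the X-linked genes were written down before their values were seen, and all others were chosen after the result was seen.

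The higher H3K9ac at erythroid genes in tg was larger than counting error allows: 15 of 18 genes with recovered reads were 2-fold higher, where the 95% range of draws ended at 2. A shift of all genes by scaling is argued against by the 51 housekeeping and ribosomal protein genes, whose median log2 ratio was -0.040 (range -1.54 to 1.21). Both libraries were scaled to their totals and the median of all genes was 0.045, so this comparison had little room to come out otherwise. It cannot exclude a difference in enrichment that acts unequally on weakly and strongly marked genes, which was not tested. A larger share of erythroid cells in the tg marrow is a candidate explanation. It needs erythroid genes outside the fixed list to be higher too, and the median of the 29 haem and transport genes was 2.42 (2.01 to 2.59). A loss of repression by GFI1B at erythroid genes within the same cells may give the same picture; it was not tested, since the table holds neither GFI1B binding nor cell counts, and with 1 library per genotype a difference between individual leukaemias stays open as well.

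The lower H3K9ac at interferon-stimulated genes in tg was also beyond counting error, with 13 of 18 genes 2-fold lower by summed reads where the 95% range of draws ended at 3. A smaller share of myeloid cells could lower them. Their median differed from that of the 17 neutrophil and monocyte genes by 0.071 (-0.88 to 0.93), so the interferon genes were not shown to be lower than the myeloid markers, and this explanation cannot be told apart from a weaker interferon response because both lists moved by about the same amount. Mx-Cre is itself activated by interferon, and how and when it was induced is not given in the sources used here.

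The Y-linked genes Uty and Ddx3y had 50 reads in WT and 1 in tg, where counting error at the pooled total allows 11 to 24 in tg. A female tg animal is a candidate explanation; loss of the Y chromosome from leukaemic cells was not tested. A female sample would raise H3K9ac at X genes that escape inactivation relative to other X genes, and the relative ratio at 4 such genes was 1.63 (1.29 to 2.05). This met the criterion written down beforehand, a ratio above 1 with an interval that excludes 1. Leaving out single genes was not part of that criterion. It showed that the result rested on Kdm6a: without this gene the ratio was 1.06 (0.742 to 1.52). The sex of the animals therefore cannot be told from these genes. If the animals differed in sex, the comparison of genotypes holds that difference too.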
